A study of Mus musculus with 36 samples.

How the data were processed

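The data were RNA-seq profiles of total RNA from 36 mouse cell cultures. Per the labels, RNA was isolated with Trizol and libraries were prepared with a NEBNext RNA kit. There were 3 cell types (trophoblast stem cells, TSCs; TSCs differentiated for 5 to 6 days by withdrawing FGF4, heparin and medium conditioned by fibroblasts; and mouse embryonic fibroblasts, MEFs). Each was given 4 treatments (control, TNFα at 20 ng/ml, IFNγ at 20 ng/ml, and both), with 3 libraries, lettered A, B and C, in each of the 12 groups. The sources used here do not give the length of treatment or say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

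The authors' notes name FastQC, Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts 2.0.1 and edgeR with the mouse genome build GRCm39, without the role or order of each. The deposited table is called counts but its values are CPM, reads scaled to a fixed total per library, with no normalization factor between libraries: every value was a whole multiple of its column's smallest step, within 0.01 reads for 100% of the values. Its columns summed to between 998455 and 1015360 CPM. Reads were therefore recovered by dividing each value by the CPM of 1 read. The recovered library sizes were 13987907 to 18956050 reads, so 1 read was 0.0528 to 0.0715 CPM. The table holds 15176 gene symbols, each read in at least 27 of the 36 libraries and 12789 in all. Genes silent in a cell type are absent. Cxcl9, Ccl5, Vcam1, Il6, Casp8 and Casp1 of the fixed panel and list genes such as Gbp5, Iigp1, Ifit1 and Mx1 had no values. Why was not tested. Another 134 symbols formed 65 sets with identical values; 1 symbol of each set was kept, which left 15107 genes. Of the symbols, 15072 matched the RefSeq annotation of GRCm38. Transcript lengths were of that build, not the authors', so no positions are given.

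Genes were kept with filterByExpr of edgeR 4.0.16 on the recovered reads (minimum 10 reads), which left 14256 genes and removed 851. The CPM values were scaled with TMM factors (0.859 to 1.10), a pseudocount of 0.5 CPM was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient for each of the 12 groups, the trend of the variance over expression, and robust moderation (24 residual degrees of freedom, median prior degrees of freedom 17.2). All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene is called, or said to have risen, fallen or changed, at an adjusted p below 0.05. Planned in advance was an edgeR quasi-likelihood test on counts, here run on the recovered reads as an alternative. Limma replaced it because the deposited values are CPM. On data simulated from these libraries with 50 genes changed at each size, limma called 66% (TSCs) and 56% (MEFs) at 1.25-fold. It called 78% and 88% at 1.5-fold and 98% and 96% at 2-fold, and 11 of 182 and 22 of 192 calls were unchanged genes. For edgeR these were 70% and 66%, 84% and 92%, 96% and 96%, and 6 of 181 and 12 of 189.

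The comparisons numbered 24. In each cell type the 3 treatments were compared with control, and an interaction asked whether the log2 effect of both cytokines differed from the sum of their single effects. The response to each treatment was compared between each pair of cell types as a difference of log2 responses, and the control groups of each pair of cell types were compared. Library letters were left out of the model.

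The choices made before the data were examined were the comparisons, the gene lists, the naming rule and most alternatives. There were 24 gene lists with 527 entries, of which 403 had values and 398 were tested. They covered JAK-STAT and IFNγ receptor signalling, interferon-inducible GTPases, interferon-stimulated antiviral genes, MHC class I and antigen processing, MHC class II, TNF receptor signalling components, NF-κB targets and feedback genes, cytokines and chemokines, nitric oxide and reactive oxygen, extrinsic and intrinsic apoptosis, apoptosis inhibitors, necroptosis and pyroptosis, p53 targets, the integrated stress and unfolded protein responses, cell cycle, cholesterol synthesis, and mitochondrially encoded genes. The other lists held markers of trophoblast stem cells, differentiated trophoblast, fibroblasts and matrix, macrophages and leukocytes, endothelium, extraembryonic endoderm and pluripotency. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 576 tests, and again with the correlation estimated from the data. Where a list's call is lost in the second test, that p is given beside it; all other list calls held. Named genes are the 6 called genes with the largest rise and the 6 with the largest fall in a comparison (mean of at least 1 CPM in a group, libraries of the 2 groups not overlapping in comparisons of 2 groups, unnamed gene models left out), a fixed panel of 34 genes of which 28 had values, and up to 4 members of each list with the smallest adjusted p.

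Alternatives fixed in advance were median-ratio size factors, library totals alone, no filter, DESeq2 1.42.0, a minimum of 2-fold, a fit of the compared cell types alone, the library letter as a block, leaving out each library, and the estimated correlation for lists. Chosen after the data were seen were limma in place of edgeR, pseudocounts of 0.1 and 1 CPM and removal of each library's trend over transcript length. So was a fit without 3 libraries that stood apart (control C and TNFα B of differentiated TSCs, and combination B of TSCs). Control A of differentiated TSCs stood apart too, in its slope over transcript length (-0.083) and in the chi-square per degree of freedom between replicate libraries (11.8 for A and B, 9.94 for A and C, 2.29 for B and C). It was kept in that fit, and another fit left it out in place of control C. Transcript lengths were available for 13925 genes (97.7%). Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. Means are of deposited CPM with the SD over 3 libraries. Intervals on read ratios are exact 95% intervals and cover counting error alone, since PCR duplicates cannot be told from independent molecules.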

Results

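The 36 libraries held 3 mouse cell types under 4 treatments, with 3 libraries in each of 12 groups. TSCs are the stem cells of trophoblast, the lineage that forms the embryo's part of the placenta, and lose the stem state when FGF4 and heparin are withdrawn. TNFα and IFNγ are inflammatory cytokines that signal mainly through NF-κB and through JAK-STAT. Library sizes were 15059029 to 18121452 reads in TSCs, 13987907 to 18448465 in differentiated TSCs and 15430130 to 18956050 in MEFs. Cell type separated the libraries far more than treatment: the first principal component, with 72.7% of the variance, parted MEFs from both trophoblast types, and the second, with 21.7%, parted TSCs from differentiated TSCs. Values are means of CPM ± SD (n = 3) or log2 differences from 1 limma fit. In the treatment comparisons, all 3 treated libraries lay beyond all 3 controls for each called gene that is named, unless overlap is stated.

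**Figure D1:**
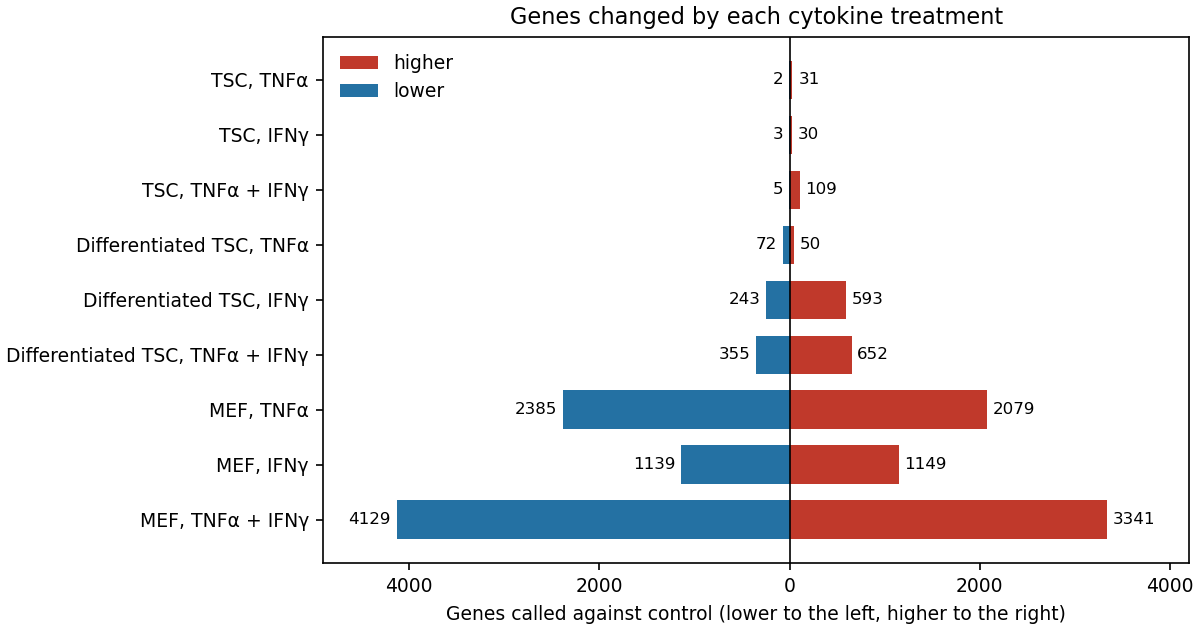
The bars give the number of genes called higher (right) or lower (left) than control at an adjusted p below 0.05 (limma) for each cell type and treatment. TSCs had 33 to 114 called genes, differentiated TSCs 122 to 1007, and MEFs 2288 to 7470.

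The first question was how the untreated cell types differed. TSCs expressed the epithelial cadherin Cdh1 at 927 ± 14.6 CPM (SD, n = 3) against 0.119 ± 0.10 in MEFs, and the trophoblast stem cell factor Elf5 at 581 ± 7.6 against 0.101 ± 0.034 (log2 difference 9.77, SE 0.092, adjusted p = 1.1e-48). The collagen gene Col1a1 stood at 2.52 ± 0.24 CPM in TSCs and 10475 ± 64.4 in MEFs (log2 difference -11.98, SE 0.097, adjusted p = 1.1e-42). Among stem cell markers 16 of 17 were higher (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.4e-08, up), with Tfap2c and Tead4 among them (9.34 and 3.49), and among fibroblast and matrix genes 21 of 21 were lower (21 adjusted over the list alone, camera adjusted p = 5.9e-13, down). IFNγ and TNFα receptors and JAK kinases were lower in TSCs. Log2 differences were -1.76 (SE 0.078, adjusted p = 5.0e-24) for Ifngr1 and -3.22 (SE 0.086, adjusted p = 1.1e-31) for Ifngr2. They were -1.93 for Jak1, -2.19 for Jak2, -1.63 (SE 0.042, adjusted p = 6.6e-33) for Tnfrsf1a and -3.52 for Tnfrsf1b. In the JAK-STAT list 4 of 20 were higher and 15 were lower (4 and 15 adjusted over the list alone, camera adjusted p = 0.010, down). Among NF-κB genes 3 of 27 were higher and 22 were lower (3 and 22 adjusted over the list alone, camera adjusted p = 6.5e-06, down). Among cytokines 13 of 14 were lower (13 adjusted over the list alone, camera adjusted p = 2.6e-05, down). In the cell cycle list, with the DNA replication gene Mcm7 at 2.11, 27 of 30 were higher and 3 were lower (27 and 3 adjusted over the list alone, camera adjusted p = 9.0e-09, up). In all 11956 genes were called, 6018 higher in TSCs and 5938 lower; with library totals alone the median log2 difference of all genes was 0.232 instead of 0.0207, and the differences above are relative to the latter.

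Differentiated TSCs were compared with MEFs in the same way. The epithelial keratin gene Krt8 stood at 5056 ± 374 CPM (SD, n = 3) against 1.26 ± 0.23 in MEFs (log2 difference 11.39, SE 0.16, adjusted p = 2.4e-28). Among differentiated trophoblast markers 13 of 14 were higher and 1 was lower (13 and 1 adjusted over the list alone, camera adjusted p = 9.3e-06, up). Among fibroblast and matrix genes 21 of 21 were lower (21 adjusted over the list alone, camera adjusted p = 8.9e-13, down). In cholesterol synthesis 1 of 21 was higher and 19 were lower (1 and 19 adjusted over the list alone, camera adjusted p = 5.1e-06, down), with Cyp51 at -2.55 and Insig1 at -2.67. Among endothelial markers, of which trophoblast giant cells express some, 6 of 7 were higher and 1 was lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.020, up). Ifngr1 (-1.72, SE 0.078, adjusted p = 9.6e-24), Ifngr2 (-1.21) and Jak1 (-0.98) were lower, while Jak2 (0.74) and Nos2 (1.87) were higher. Stat1 was not called, at 0.14 (SE 0.092, adjusted p = 0.17), but was called at 0.26 (adjusted p = 0.00935) with library totals alone. The count was 11932 genes (5986 higher and 5946 lower); with library totals alone the median log2 difference of all genes was 0.130 instead of 0.0128.

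Differentiation itself was followed by comparing both kinds of TSC. The stem markers Elf5 and Sox2 were lower in differentiated TSCs (-3.81, SE 0.092, adjusted p = 3.3e-33 and -5.64, SE 0.18, adjusted p = 3.5e-29), as was Id2, an inhibitor of differentiation (-6.34, 3.78 ± 3.6 against 301 ± 1.4 CPM, SD, n = 3). The hormone genes Prl3d1 (4.98, SE 0.11, adjusted p = 3.8e-34) and Prl2c2 (5.98) and the lipid regulator Pparg (4.81) were higher, and among differentiated trophoblast markers 11 of 14 were higher and 3 were lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.0019, up). Stem cell markers went both ways: 6 of 17 were higher and 11 were lower (6 and 11 adjusted over the list alone, camera adjusted p = 0.14), with Gata2 (2.52) and Ets2 (1.86) among the higher ones. Cell cycle genes such as Plk1 and Cdc20 were lower (-1.77 and -2.11), and in the list 2 of 30 were higher and 28 were lower (2 and 28 adjusted over the list alone, camera adjusted p = 3.5e-12, down). In the cholesterol list 2 of 21 were higher and 15 were lower (2 and 15 adjusted over the list alone, camera adjusted p = 2.0e-04, down). In the JAK-STAT list 13 of 20 were higher and 3 were lower (13 and 3 adjusted over the list alone, camera adjusted p = 0.0060, up), with Jak2 at 2.94, Ifngr2 at 2.01 and Stat1 at 1.68, while Ifngr1 was not called (0.03, SE 0.078, adjusted p = 0.71). Of the genes tested 10896 were called, 5395 higher and 5501 lower; with library totals alone the median of all genes was -0.111 instead of -0.0201. Of the 11 stem cell markers lower in differentiated TSCs, 9 were highest in control C among the 3 controls (0 in A and 2 in B), Eomes for example at 14.3 CPM against 6.96 in A and 5.80 in B, a comparison made after the values were seen.

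TNFα in TSCs raised a small set of NF-κB feedback genes. Nfkbia, which encodes the inhibitor IκBα, stood at 48.2 ± 2.4 CPM (SD, n = 3) against 31.6 ± 1.9 in control (log2 difference 0.61, SE 0.055, adjusted p = 3.2e-10). Map3k14, a kinase of the noncanonical NF-κB pathway, rose from 9.22 ± 1.4 to 14.6 ± 1.1 CPM (log2 difference 0.65, SE 0.087, adjusted p = 1.4e-05), Nfkb2 rose by 0.49 (SE 0.043, adjusted p = 3.2e-10), Relb by 0.55 (SE 0.080, adjusted p = 5.6e-05) and Tnip1 by 0.31 (SE 0.048, adjusted p = 1.4e-04) on the log2 scale. Among NF-κB genes 7 of 27 rose (11 adjusted over the list alone, camera adjusted p = 1.2e-23, up). Among cytokines 1 of 14 rose (4 adjusted over the list alone, camera adjusted p = 8.6e-08, up). Among p53 targets 1 of 22 rose (1 adjusted over the list alone, camera adjusted p = 0.0020, up). In the list of differentiated trophoblast markers no gene passed over all genes, but the list test gave adjusted p = 0.039, up, and adjusted p = 0.070 with an estimated correlation. The count was 33 genes, 31 higher and 2 lower, with a change of at least 2-fold in 0 of them (616 had an unadjusted p below 0.05). It was 20 without TNFα A, 19 without TNFα C and 53 with a fit of TSC libraries alone. The 3 largest rises were those of Nme2 (0.69), Tnfaip3 (0.69) and Saa3 (0.66), but the call of Tnfaip3 ended without control A, control B or TNFα C, that of Saa3 without control B, control C or TNFα B, and that of Nme2 without any 1 library other than control B. Saa3 was not called with edgeR (adjusted p = 0.401), DESeq2 (adjusted p = 0.188), a pseudocount of 0.1 CPM (adjusted p = 0.429) or TSC libraries alone (adjusted p = 0.345), Nme2 not with edgeR (adjusted p = 0.076) and Tnfaip3 not with TSC libraries alone (adjusted p = 0.053).

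IFNγ in TSCs raised interferon response genes. Irf1, a transcription factor of that response, rose from 9.23 ± 0.69 to 39.5 ± 2.7 CPM (SD, n = 3; log2 difference 2.05, SE 0.080, adjusted p = 9.4e-23), and Gbp2, a GTPase of cell-autonomous defence, from 0.0951 ± 0.16 to 3.26 ± 0.76 (log2 difference 2.58, SE 0.17, adjusted p = 2.4e-11), from 5 control reads, so the size of its rise depends on the pseudocount. Irgm2 reached 7.27 ± 0.50 CPM from 1.11 ± 0.50, and Stat1 rose by 1.39 (SE 0.092, adjusted p = 1.7e-14). Of the interferon-inducible GTPases with values, 7 of 7 rose (7 adjusted over the list alone, camera adjusted p = 5.7e-67, up). In antigen processing 8 of 21 rose (14 adjusted over the list alone, camera adjusted p = 1.7e-29, up), with the peptide transporter genes Tap1 (0.48) and Tap2 (0.45) and the trimming enzyme Erap1 (0.60) among them, whereas the MHC class I gene H2-K1 was not called (0.16, SE 0.055, adjusted p = 0.49). In JAK-STAT signalling 4 of 20 rose (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.4e-13, up). In the antiviral list 3 of 27 rose (5 adjusted over the list alone, camera adjusted p = 1.9e-11, up, adjusted p = 0.051 with an estimated correlation), with Parp14 (1.55) and Dtx3l (0.98) among them, and among NF-κB genes 1 of 27 rose (5 adjusted over the list alone, camera adjusted p = 5.7e-05, up). Of the mitochondrially encoded transcripts 3 of 13 fell (7 adjusted over the list alone, camera adjusted p = 4.6e-19, down), with a median of -0.23, and COX1 fell (-0.21, SE 0.039, adjusted p = 0.0029) from 6183 ± 202 to 5318 ± 214 CPM, a call that ended without control A (adjusted p = 0.06) or IFNγ A (adjusted p = 0.0657) and with a fit of TSC libraries alone (adjusted p = 0.163). The count was 33 genes, 30 higher and 3 lower, 11 of them at least 2-fold.

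Both cytokines together raised NF-κB and interferon genes in TSCs. Gbp2 stood at 2.81 ± 0.75 CPM (SD, n = 3; log2 difference 2.41, SE 0.17, adjusted p = 9.3e-11), Irf1 at 38.9 ± 3.3 (2.04) and Nfkbia at 49.5 ± 1.9 (0.66, SE 0.055, adjusted p = 6.8e-12). The adhesion gene Icam1 rose by 0.53 (SE 0.077, adjusted p = 1.1e-05), the growth factor gene Csf1 by 0.51 and the MHC class I genes H2-D1 and H2-K1 by 0.36 and 0.33. Among NF-κB genes 8 of 27 rose (16 adjusted over the list alone, camera adjusted p = 2.2e-25, up). Among GTPases 6 of 7 rose (7 adjusted over the list alone, camera adjusted p = 3.3e-50, up). In antigen processing 9 of 21 rose (16 adjusted over the list alone, camera adjusted p = 1.7e-27, up). In JAK-STAT signalling 5 of 20 rose (9 adjusted over the list alone, camera adjusted p = 7.6e-16, up). Among cytokines 2 of 14 rose (6 adjusted over the list alone, camera adjusted p = 1.3e-05, up). Among antiviral genes 3 of 27 rose (4 adjusted over the list alone, camera adjusted p = 9.7e-08, up, adjusted p = 0.12 with an estimated correlation). Reads of the chemokine genes were few: Ccl2 had 36 reads over the 3 treated libraries against 1 in control (ratio 36.5, 95% interval 6.14 to 1481), and Cxcl10 had 25 against 2 (ratio 12.7, 3.16 to 110). Mitochondrially encoded genes were lower as a list (camera adjusted p = 4.1e-06), which was lost with an estimated correlation (adjusted p = 0.15), and among fibroblast genes 2 of 21 fell (2 adjusted over the list alone, camera adjusted p = 0.021, down, adjusted p = 0.18 with an estimated correlation). The count was 114 genes, 109 higher and 5 lower, 12 at least 2-fold. It was 74 without control B, and 255 with a fit of TSC libraries alone (194 higher and 61 lower).

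No gene passed the interaction test in TSCs: limma, edgeR and DESeq2 each called 0 genes, and 431 had an unadjusted p below 0.05 in limma. A count of 1 was reached without control A or without TNFα B, and of 2 without the 3 libraries that stood apart. Icam1 in the combination stood at 63.4 CPM, and the control level plus both single changes, the additive level, came to 63.9 CPM. At few reads, Cxcl10 stood at 0.496 CPM against an additive level of 0.0852 (difference 0.411, SE 0.068) and Zbp1 at 0.179 against 0.0376 (difference 0.141, SE 0.038), each above that level in 3 of 3 libraries. Mitochondrially encoded genes were higher as a list (adjusted p = 5.1e-05), with adjusted p = 0.21 with an estimated correlation, and GTPases lower (adjusted p = 0.019), with adjusted p = 0.13 with an estimated correlation.

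**Figure D2:**
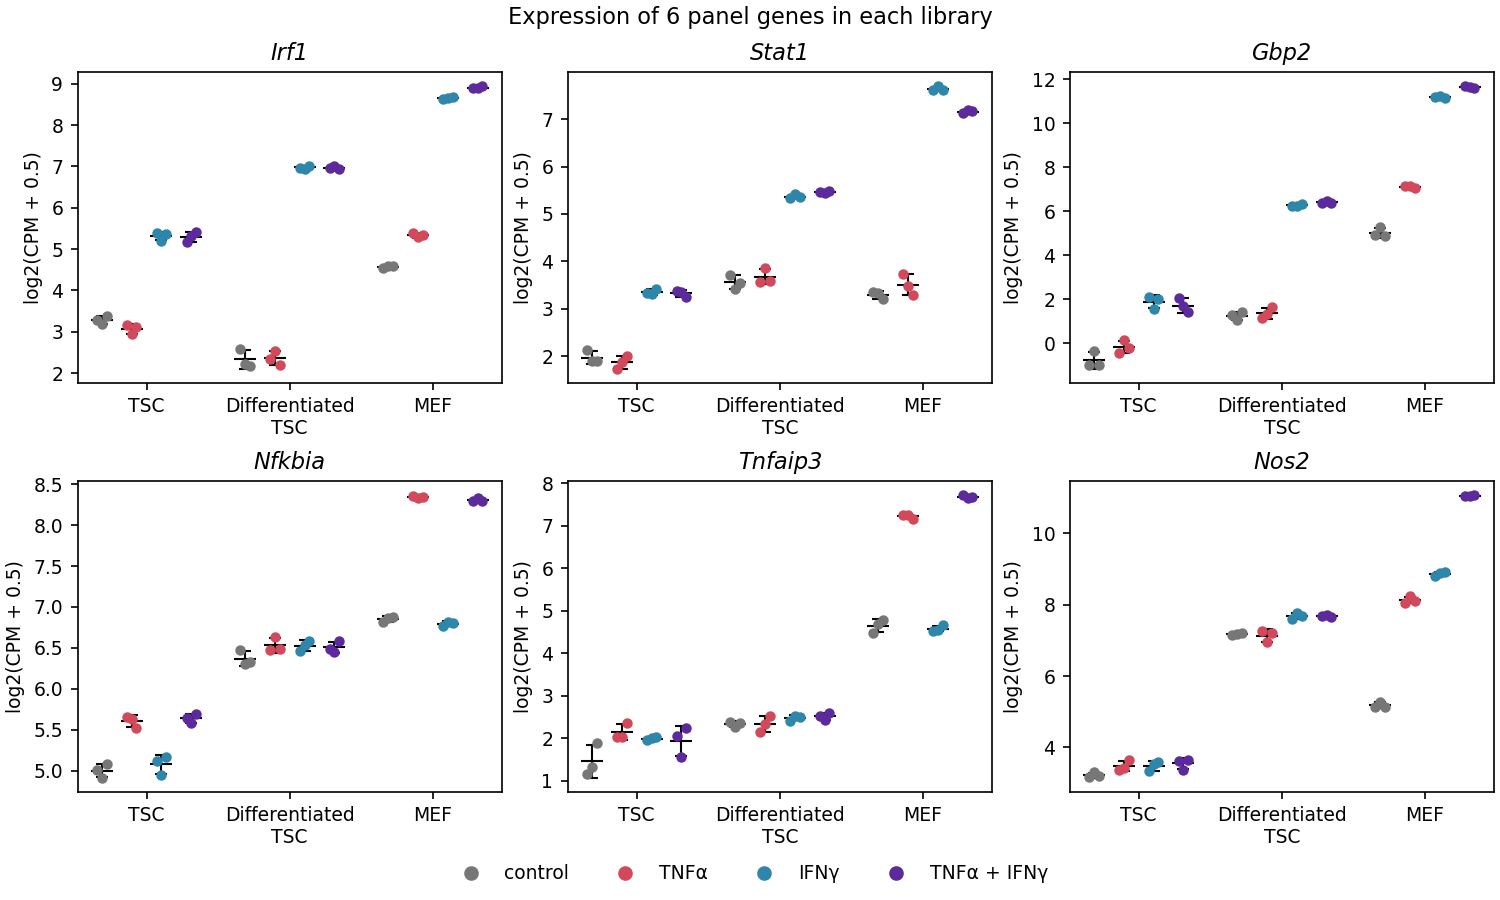
Each point is log2 of CPM plus 0.5 of a panel gene in 1 library, by cell type and treatment, with the group mean and SD (n = 3) as bars. Irf1 in IFNγ-treated libraries averaged 39.5 CPM in TSCs and 125 in differentiated TSCs, and Nfkbia averaged 48.2 CPM in TSCs with TNFα against 31.6 in control.

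TNFα in differentiated TSCs gave a count of changes that rested on a few libraries. The chemokine gene Ccl2 stood at 1.23 ± 0.29 CPM (SD, n = 3) against 0.378 ± 0.10 (log2 difference 0.96, SE 0.16, adjusted p = 0.0022), and Ndst1, an enzyme of heparan sulphate synthesis, fell from 11.3 ± 2.1 to 7.07 ± 1.5 (log2 difference -0.64, SE 0.093, adjusted p = 6.2e-04). The imprinted gene Mest fell by 0.63 (SE 0.13, adjusted p = 0.015), while the feedback genes Nfkbia and Tnfaip3 were not called (0.17, SE 0.055, adjusted p = 0.086 and 0.01, SE 0.13, adjusted p = 0.98; Nfkbia had adjusted p = 0.0283 with DESeq2). Among NF-κB genes no gene passed over all genes, 4 were higher and 1 lower adjusted over the list alone, and the list test gave adjusted p = 0.014, up, with adjusted p = 0.16 with an estimated correlation. Antigen processing (adjusted p = 0.0015) and the stress response list (adjusted p = 0.016) were also up, and cell cycle (adjusted p = 0.0069) and stem cell markers (adjusted p = 0.022) down, but with an estimated correlation these gave adjusted p = 0.17, adjusted p = 0.22, adjusted p = 0.36 and adjusted p = 0.24. Without control C cell cycle had adjusted p = 0.092 and stem cell markers adjusted p = 0.68. The count was 122 genes, 50 higher and 72 lower. It was 2262 without control A, 21 without control B, 12 without control C, 9 without TNFα B and 2067 without TNFα C. Without the 3 libraries that stood apart it was 8 (3 higher and 5 lower), and 641 (166 higher and 475 lower) with control A left out in place of control C. Ccl2 was not called without TNFα B (adjusted p = 0.0574), nor Mest without TNFα B (adjusted p = 0.318) or control C (adjusted p = 0.162), nor with edgeR (adjusted p = 0.0616). The called higher genes had a median transcript length of 2170 bases and the lower ones 7510, against 4311 for all genes, and 64 genes were called after each library's length trend was removed, 46 of them from the 122. With a fit of differentiated TSC libraries alone limma called 0 genes; in the fit of all libraries 2822 genes had an unadjusted p below 0.05, edgeR called 127 and DESeq2 755.

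**Figure D3:**
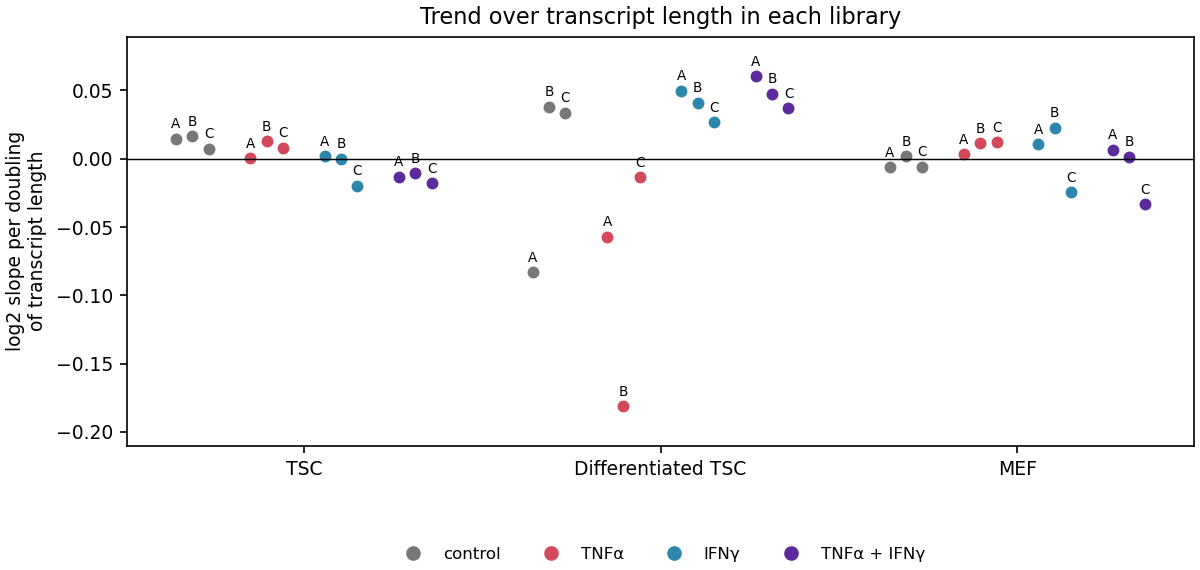
Each point is the change in 1 library's log2 values per doubling of transcript length, taken against the mean of its cell type, by group. TNFα B of the differentiated TSCs had a slope of -0.181 and control A of -0.0830, whereas the libraries of the other cell types lay between -0.0334 and 0.0227.

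IFNγ in differentiated TSCs raised the interferon response by large factors. Gbp7 rose from 0.200 ± 0.19 to 33.7 ± 0.68 CPM (SD, n = 3; log2 difference 5.66, SE 0.15, adjusted p = 5.1e-30), Gbp2 from 1.87 ± 0.28 to 76.7 ± 2.9 (log2 difference 5.06, SE 0.17, adjusted p = 3.6e-19), Igtp from 5.27 ± 0.43 to 148 ± 4.1 and Irf1 from 4.57 ± 0.80 to 125 ± 3.6 (log2 difference 4.67, SE 0.080, adjusted p = 4.5e-37). Among GTPases 7 of 7 rose (7 adjusted over the list alone, camera adjusted p = 3.8e-55, up), with a median of 4.72. Among antiviral genes 19 of 27 rose (22 adjusted over the list alone, camera adjusted p = 1.1e-47, up), with Parp14 at 4.54 and Dtx3l at 4.36. In antigen processing 16 of 21 rose and 1 fell (17 and 2 adjusted over the list alone, camera adjusted p = 7.6e-46, up): Tap1 rose by 2.97 (SE 0.059, adjusted p = 1.1e-34), the immunoproteasome gene Psmb8 by 2.81, B2m by 0.80 and H2-K1 by 0.47. In JAK-STAT signalling 10 of 20 rose (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.6e-19, up), and Stat1 rose by 1.84 and the feedback inhibitor Socs1 by 1.57.

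Genes of cell death and inflammation also rose with IFNγ in these cells. The nucleic acid sensor Zbp1 rose by 2.83 (SE 0.18, adjusted p = 5.3e-16), the necroptosis effector Mlkl by 1.02 (SE 0.099, adjusted p = 1.5e-10) and the pyroptosis effector Gsdmd by 0.83. In that list 5 of 9 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 2.1e-04, up). Among apoptosis genes 7 of 22 rose and 2 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0025, up), with Xaf1 (3.07) and Casp7 (0.59) among them, and among TNF receptor components 5 of 27 rose (6 adjusted over the list alone, camera adjusted p = 0.0030, up). The chemokine gene Cxcl10 rose by 2.84 (SE 0.28, adjusted p = 1.4e-08) and Csf1 by 0.94. Among cytokines 4 of 14 rose (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.9e-04, up). Among NF-κB genes 4 of 27 rose (4 adjusted over the list alone, camera adjusted p = 9.8e-04, up, adjusted p = 0.061 with an estimated correlation), with Icam1 at 1.70. The peptide hormone gene Apln fell (-0.84, SE 0.16, adjusted p = 2.9e-04; adjusted p = 0.092 with a fit of differentiated TSC libraries alone), and so did the stem cell factor Elf5 (-0.49, SE 0.092, adjusted p = 2.4e-04; adjusted p = 0.0744 with a pseudocount of 0.1 CPM). Elf5 stood at 46.2 CPM in control C against 37.2 in A and 31.8 in B, and at -0.35 (adjusted p = 0.014) without control C. In the cell cycle list 1 of 30 rose and 4 fell (1 and 8 adjusted over the list alone, camera adjusted p = 1.2e-04, down, adjusted p = 0.18 with an estimated correlation); without control C, in which 17 of the 28 cell cycle genes lower in differentiated TSCs than in TSCs were highest among the controls, 3 fell (camera adjusted p = 0.015). The cholesterol genes were lower as a list (adjusted p = 0.046), with adjusted p = 0.21 with an estimated correlation. Of the mitochondrially encoded transcripts 8 of 13 fell (11 adjusted over the list alone, camera adjusted p = 1.1e-11, down), with COX1 at -0.29 (SE 0.039, adjusted p = 3.3e-07) and CYTB at -0.34. The count was 836 genes, 593 higher and 243 lower (72 and 1 at least 2-fold), and with library totals alone 472 higher and 493 lower. It was 507 without control A, 556 without IFNγ C, 361 with a fit of differentiated TSC libraries alone (312 higher and 49 lower) and 1558 without the 3 libraries that stood apart. The called higher genes had a median transcript length of 5591 bases and the lower ones 3523, against 4311 for all genes. The slopes over transcript length were 0.0499, 0.0409 and 0.0268 with IFNγ, against -0.083 in control A and 0.0382 and 0.0338 in controls B and C. After each library's length trend was removed 746 of the 836 genes were still called.

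Both cytokines in differentiated TSCs raised interferon genes and further inflammatory genes. Gbp7 rose by 5.79 (SE 0.15, adjusted p = 2.0e-30), Irf1 by 4.66 to 125 ± 4.0 CPM (SD, n = 3), and Cxcl10 by 3.48 (SE 0.28, adjusted p = 1.7e-10). Ccl2 rose by 1.71, the acute phase gene Saa3 by 0.78, the IκB family member Bcl3 by 0.82 and Ptgs2, the inducible cyclooxygenase, by 1.00. Among NF-κB genes 9 of 27 rose (11 adjusted over the list alone, camera adjusted p = 6.8e-08, up). Among GTPases 7 of 7 rose (7 adjusted over the list alone, camera adjusted p = 1.8e-53, up). Among antiviral genes 20 of 27 rose (22 adjusted over the list alone, camera adjusted p = 2.7e-45, up). In antigen processing 16 of 21 rose (17 adjusted over the list alone, camera adjusted p = 2.1e-46, up). The trophoblast gene Ascl2 fell by 0.72 (SE 0.14, adjusted p = 2.7e-04). In the cell cycle list 1 of 30 rose and 12 fell (1 and 15 adjusted over the list alone, camera adjusted p = 6.0e-09, down), with Aurka at -0.32 (SE 0.056, adjusted p = 7.9e-05) and Plk1 at -0.22, although Ccnd1 rose by 0.49. Without control C, in which many of these genes stood highest among the controls (17 of 28), 8 of the list fell (camera adjusted p = 1.6e-05). Among mitochondrially encoded genes 8 of 13 fell (10 adjusted over the list alone, camera adjusted p = 3.2e-11, down). Among p53 targets 2 of 22 fell (2 adjusted over the list alone, camera adjusted p = 0.032, down). The count was 1007 genes, 652 higher and 355 lower (75 and 1 at least 2-fold), and with library totals alone 500 higher and 582 lower. It was 583 without control A, 643 without combination A, 665 without combination C, 458 with a fit of differentiated TSC libraries alone (353 higher and 105 lower) and 1750 without the 3 libraries that stood apart. Higher genes again had longer transcripts than lower ones (medians 5752 and 3404 bases), and 853 of the 1007 were still called after the length trend was removed.

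The interaction test in differentiated TSCs called 7 genes, 4 higher and 3 lower. Efnb2, a ligand of Eph receptors, was higher in the combination than the single effects add up to (log2 difference 0.76, SE 0.099, adjusted p = 2.5e-05), as were the adhesion receptor gene Adgra2 (0.74), Tpst1 (0.69, SE 0.12, adjusted p = 0.0091) and Socs5 (0.48, SE 0.083, adjusted p = 0.0061). Wdr54, Twist2 and Dlk1 were lower (-1.20, -1.05 and -0.74), and each of these calls ended without control B, without TNFα B and without IFNγ C. That of Adgra2 ended without control B or combination A. That of Wdr54 also ended without combination C, that of Twist2 without control C, TNFα A, combination A or combination B, and that of Dlk1 without control C, IFNγ A or any 1 combination library. Efnb2 was the gene that edgeR called. The antigen processing list was lower (adjusted p = 0.043), with adjusted p = 0.40 with an estimated correlation, and stem cell markers higher (adjusted p = 0.027), with adjusted p = 0.26 with an estimated correlation and adjusted p = 0.42 without control C. The count was 752 without control A, 625 without TNFα C, 11 without IFNγ B, 4 without IFNγ C and 4 without combination A. It was 7 higher and 3 lower with library totals alone, 0 with a fit of differentiated TSC libraries alone, 1 with edgeR, 12 with DESeq2 (9 higher and 3 lower) and 16 with a pseudocount of 0.1 CPM (12 higher and 4 lower). With control A and 2 other libraries left out it was 286 (213 higher and 73 lower).

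TNFα in MEFs changed many inflammatory, metabolic and matrix genes. Mmp9, a matrix protease, rose from 5.84 ± 0.78 to 121 ± 9.8 CPM (SD, n = 3; log2 difference 4.29, SE 0.12, adjusted p = 3.2e-27), and the cytokine gene Il1a from 0.889 ± 0.098 to 15.5 ± 0.69. Nos2, the inducible nitric oxide synthase, rose by 2.97 (SE 0.075, adjusted p = 2.7e-27), Tnfaip3 by 2.59, Nfkbia by 1.51 and Cxcl1 by 2.05. Among NF-κB genes 23 of 27 rose and 2 fell (23 and 2 adjusted over the list alone, camera adjusted p = 6.5e-33, up). Among cytokines 13 of 14 rose (13 adjusted over the list alone, camera adjusted p = 2.3e-20, up). In the nitric oxide and reactive oxygen list 10 of 15 rose (11 adjusted over the list alone, camera adjusted p = 5.8e-16, up), with Gch1 and Ass1 among them (1.57 and 1.71). In antigen processing 14 of 21 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.5e-09, up). Among GTPases 4 of 7 rose (4 adjusted over the list alone, camera adjusted p = 0.0061, up, adjusted p = 0.078 with an estimated correlation). Among antiviral genes 11 of 27 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.0011, up, adjusted p = 0.37 with an estimated correlation). Among necroptosis genes 4 of 9 rose (4 adjusted over the list alone, camera adjusted p = 0.012, up). In cholesterol synthesis 21 of 21 fell (21 adjusted over the list alone, camera adjusted p = 5.6e-18, down), with a median of -0.65 and Hmgcs1 at -0.91 (SE 0.056, adjusted p = 2.0e-17). Sned1, a matrix gene, fell from 155 ± 6.0 to 19.4 ± 0.87 CPM (log2 difference -2.96, SE 0.14, adjusted p = 1.3e-20), and the elastin gene Eln fell by 2.60. Among fibroblast and matrix genes 2 of 21 rose and 10 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0081, down, adjusted p = 0.12 with an estimated correlation). In the cell cycle list 1 of 30 rose and 19 fell (1 and 20 adjusted over the list alone, camera adjusted p = 4.6e-06, down, adjusted p = 0.10 with an estimated correlation). The count was 4464 genes, 2079 higher and 2385 lower, of which 228 and 178 changed at least 2-fold.

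IFNγ in MEFs raised interferon response genes by large factors. Igtp rose from 3.07 ± 0.69 to 836 ± 19.5 CPM (SD, n = 3; log2 difference 7.89, SE 0.17, adjusted p = 3.7e-24), Cxcl10 from 3.66 ± 2.6 to 410 ± 32.9 (log2 difference 6.79, SE 0.28, adjusted p = 7.2e-18) and Gbp2 from 32.2 ± 5.1 to 2343 ± 42.4. Stat1 rose by 4.34 (SE 0.092, adjusted p = 4.6e-34), Irf1 by 4.07 and Socs1 by 2.91. Among antiviral genes 27 of 27 rose (27 adjusted over the list alone, camera adjusted p = 4.5e-75, up), with a median of 2.77. In antigen processing 19 of 21 rose (19 adjusted over the list alone, camera adjusted p = 1.0e-76, up), with H2-K1 at 2.60 (SE 0.055, adjusted p = 5.2e-34) and B2m at 1.63. Among MHC class II genes 5 of 6 rose (5 adjusted over the list alone, camera adjusted p = 4.1e-08, up), with the transactivator Ciita at 3.16 (SE 0.20, adjusted p = 5.4e-17) and Cd74 at 2.47. Among GTPases 6 of 7 rose (6 adjusted over the list alone, camera adjusted p = 2.7e-30, up). In JAK-STAT signalling 11 of 20 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 3.1e-16, up). Among necroptosis genes 6 of 9 rose (6 adjusted over the list alone, camera adjusted p = 6.9e-13, up), with Zbp1 at 5.79 and Mlkl at 2.03. Among apoptosis genes 6 of 22 rose (6 adjusted over the list alone, camera adjusted p = 1.1e-04, up).

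Other gene groups also moved with IFNγ in MEFs. Among cytokines 9 of 14 rose (10 adjusted over the list alone, camera adjusted p = 1.3e-12, up). In the nitric oxide list 6 of 15 rose (6 adjusted over the list alone, camera adjusted p = 2.7e-07, up), with Nos2 at 3.67 (SE 0.075, adjusted p = 1.1e-30). Among TNF receptor components 7 of 27 rose (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.018, up, adjusted p = 0.052 with an estimated correlation). Among matrix genes 9 of 21 fell (9 adjusted over the list alone, camera adjusted p = 2.9e-04, down), with Aspn (-1.61, SE 0.23, adjusted p = 4.4e-07) and Eln (-1.45) among the largest falls of the comparison, and in cholesterol synthesis 12 of 21 fell (12 adjusted over the list alone, camera adjusted p = 3.9e-05, down). Among cell cycle genes 11 of 30 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.0031, up, adjusted p = 0.31 with an estimated correlation), with Top2a at 0.48. In the stress response list 3 of 23 rose and 10 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.027, down, adjusted p = 0.26 with an estimated correlation), with Trib3 at -0.57. The count was 2288 genes, 1149 higher and 1139 lower, with 207 and 16 changed at least 2-fold.

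Both cytokines together changed more MEF genes than any other treatment comparison here, 7470. Cxcl10 reached 1794 ± 45.1 CPM (SD, n = 3; log2 difference 9.04, SE 0.28, adjusted p = 1.5e-21) and Nos2 rose from 35.9 ± 2.1 to 2137 ± 6.7 (log2 difference 5.98, SE 0.075, adjusted p = 9.6e-38). Neurl3, a ubiquitin ligase gene, rose from 2.72 ± 0.69 to 329 ± 4.6 CPM, Icam1 rose by 4.19 (SE 0.077, adjusted p = 6.2e-37) and Il1a by 5.38. In antigen processing 21 of 21 rose (21 adjusted over the list alone, camera adjusted p = 3.2e-29, up). Among antiviral genes 27 of 27 rose (27 adjusted over the list alone, camera adjusted p = 5.6e-23, up). Among cytokines and chemokines 14 of 14 rose (14 adjusted over the list alone, camera adjusted p = 2.3e-15, up). Among NF-κB genes 24 of 27 rose and 2 fell (24 and 2 adjusted over the list alone, camera adjusted p = 2.3e-23, up). In the nitric oxide list 12 of 15 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 7.9e-12, up), with the oxidative stress gene Srxn1 at 2.12, and in the necroptosis list 7 of 9 rose (7 adjusted over the list alone, camera adjusted p = 6.4e-06, up). In the stress response list 13 of 23 rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.0018, up, adjusted p = 0.11 with an estimated correlation), with Atf3 at 2.48 and Slc7a11 at 4.30. In cholesterol synthesis 20 of 21 fell (20 adjusted over the list alone, camera adjusted p = 8.6e-13, down), with Hmgcs1 at -1.46 (SE 0.056, adjusted p = 3.0e-25). Among matrix genes 1 of 21 rose and 16 fell (1 and 16 adjusted over the list alone, camera adjusted p = 9.1e-05, down), with Col3a1 at -1.79 (SE 0.17, adjusted p = 2.0e-11). In the cell cycle list 4 of 30 rose and 19 fell (4 and 19 adjusted over the list alone, camera adjusted p = 4.7e-04, down, adjusted p = 0.22 with an estimated correlation). Among apoptosis genes 12 of 22 rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.0044, up). Among apoptosis inhibitors 6 of 11 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.19). Among MHC class II genes 3 of 6 rose (3 adjusted over the list alone, camera adjusted p = 0.016, up), with H2-Ab1 at 3.44. There were 3341 genes higher and 4129 lower (672 and 514 at least 2-fold); with library totals alone there were 2419 higher and 5644 lower, with a median log2 difference of all genes of -0.131 instead of -0.0416.

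The interaction in MEFs asked where the combination departed from the sum of the log2 effects, and 1282 genes did, 769 higher and 513 lower. Ndrg1, a stress response gene, stood at 122 ± 1.2 CPM (SD, n = 3) with both cytokines, against 24.7 ± 2.3 with TNFα, 25.0 ± 1.2 with IFNγ and 24.5 ± 1.5 in control (log2 difference 2.35, SE 0.17, adjusted p = 4.3e-11). The calcium channel gene Cacna1h stood at 14.6 ± 1.2 CPM, against 2.22 ± 0.19, 7.73 ± 0.31 and 11.3 ± 1.3 in the same order (log2 difference 3.11, SE 0.23, adjusted p = 1.2e-11). In the stress response list 11 of 23 were higher (11 adjusted over the list alone, camera adjusted p = 3.9e-11, up), with Trib3 at 1.72 (SE 0.13, adjusted p = 2.7e-13), Ppp1r15a at 0.93, Atf3 at 1.43 and Atf4 at 0.55. In the nitric oxide and reactive oxygen list 4 of 15 were higher and 2 were lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.0033, up), with Hmox1 at 1.30 (SE 0.061, adjusted p = 1.1e-19) and Srxn1 at 0.84, although Nos2 was lower (-0.66, SE 0.11, adjusted p = 3.0e-05). Among NF-κB genes 5 of 27 were higher and 1 was lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0044, up, adjusted p = 0.11 with an estimated correlation), with Icam1 at 0.59. Among antiviral genes 8 of 27 were lower (17 adjusted over the list alone, camera adjusted p = 4.9e-10, down, adjusted p = 0.071 with an estimated correlation), with Parp14 at -0.74; Gbp2 (-1.54, SE 0.24, adjusted p = 4.4e-05) and Stat1 (-0.60) were lower too. Among cell cycle genes 1 of 30 was higher and 12 were lower (1 and 15 adjusted over the list alone, camera adjusted p = 4.1e-08, down, adjusted p = 0.051 with an estimated correlation), with Ccnb1 at -0.39. The class II transactivator Ciita stood at 1.73 ± 0.35 CPM with both, against 6.34 ± 0.42 with IFNγ (log2 difference -1.54, SE 0.28, adjusted p = 1.2e-04; adjusted p = 0.0806 with edgeR and adjusted p = 0.104 with a pseudocount of 0.1 CPM). With a fit of MEF libraries alone 2180 genes were called, 1208 higher and 972 lower. With library totals alone 470 genes were higher and 1416 lower, and the GTPase list, lower here (adjusted p = 0.011, and adjusted p = 0.10 with an estimated correlation), had adjusted p = 0.0563.

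On the scale of CPM itself the MEF combination can be set against an additive level, the control level plus both single changes. Cxcl10 stood at 1794 CPM against 425.8 (difference 1368, SE 32.4), and Nos2 at 2136 against 713 (difference 1423, SE 15.2). Icam1 stood at 646 CPM against 230.4 (difference 415, SE 4.97). Gbp2 was above its additive level too, at 3192 CPM against 2448 (difference 745, SE 46.0, above in 3 of 3 libraries), although its log2 interaction was below 0 (-1.54). Stat1 was below its additive level, at 143 CPM against 201 (difference -58.8, SE 4.06), as was Ciita, at 1.73 against 6.34. For Cxcl10 the log2 interaction was not called (-0.15, SE 0.40, adjusted p = 0.89).

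**Figure D4:**
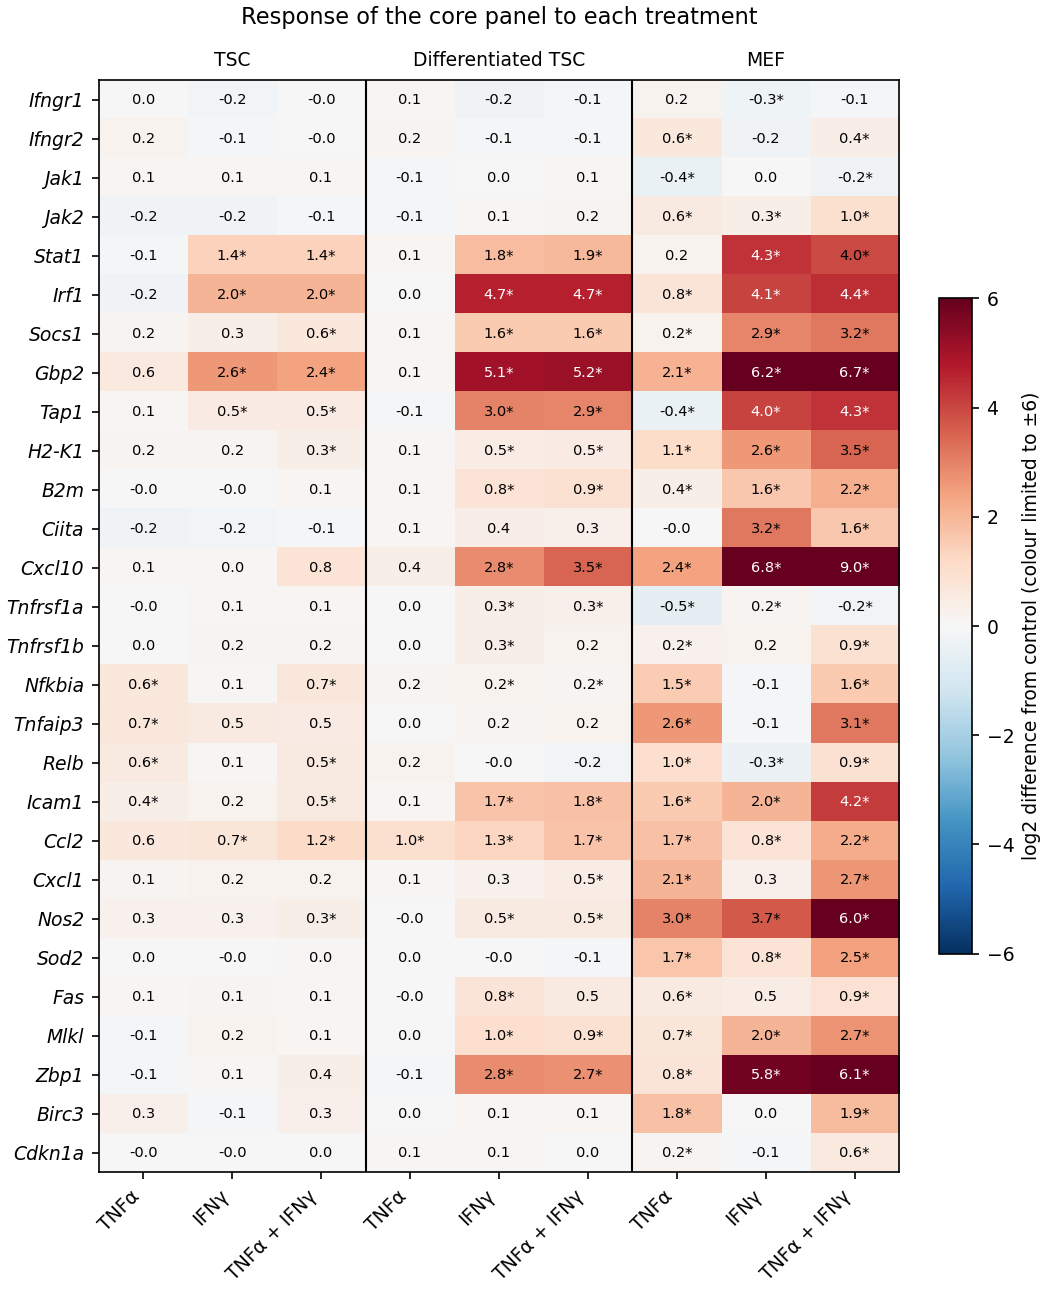
The heatmap gives the log2 difference from control (colour) of each gene of the fixed panel in each cell type and treatment, with colour limited at 6 and -6 and asterisks on called values. Stat1 with IFNγ was at 1.39 in TSCs, 1.84 in differentiated TSCs and 4.34 in MEFs.

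Log2 responses of TSCs and MEFs were compared directly, as TSCs minus MEFs. With TNFα, Mmp9 responded less in TSCs (log2 difference -4.24, SE 0.17, adjusted p = 1.7e-21), as did Nos2 (-2.72, SE 0.11, adjusted p = 6.0e-21), Tnfaip3 (-1.90, SE 0.19, adjusted p = 1.7e-10) and Nfkbia (-0.90, SE 0.077, adjusted p = 2.6e-12), while the falls of Sned1 and Eln in MEFs gave positive differences (3.14 and 2.97). Among NF-κB genes 1 of 27 was higher and 21 were lower (2 and 21 adjusted over the list alone, camera adjusted p = 4.8e-32, down). Among cytokines 12 of 14 responded less (12 adjusted over the list alone, camera adjusted p = 1.7e-19, down). In cholesterol synthesis (falls in MEFs) 21 of 21 were higher (21 adjusted over the list alone, camera adjusted p = 8.5e-20, up). With IFNγ, Igtp responded less in TSCs (log2 difference -6.18, SE 0.24, adjusted p = 1.5e-17), as did Stat1 (-2.96, SE 0.13, adjusted p = 8.0e-22), Irf1 (-2.03), Tap1 (-3.56) and H2-K1 (-2.44, SE 0.077, adjusted p = 9.1e-27). Among antiviral genes 27 of 27 were lower (27 adjusted over the list alone, camera adjusted p = 1.6e-73, down). In antigen processing 19 of 21 were lower (19 adjusted over the list alone, camera adjusted p = 1.6e-83, down). Among GTPases 1 of 7 was higher and 6 were lower (1 and 6 adjusted over the list alone, camera adjusted p = 7.0e-23, down); Gbp2 and Gbp2b, with 5 and 8 reads in TSC controls, were not called with DESeq2 (adjusted p = 0.35 and adjusted p = 0.263) or edgeR (adjusted p = 0.59 and adjusted p = 0.427). With both cytokines Nos2 differed by -5.64 (SE 0.11, adjusted p = 1.8e-31), Neurl3 by -6.95 and Sned1 by 4.11. The counts were 2607 genes with TNFα (1418 higher and 1189 lower in TSCs), 1231 with IFNγ (561 and 670) and 5436 with both (2980 and 2456). With library totals alone the last was 3877 higher and 1976 lower, with a median of all genes of 0.110.

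The same test set differentiated TSCs against MEFs. With TNFα, Mmp9 (log2 difference -4.04, SE 0.17, adjusted p = 5.5e-21), Tnfaip3 (-2.58, SE 0.19, adjusted p = 2.5e-14), Nos2 (-3.01) and Nfkbia (-1.34, SE 0.077, adjusted p = 1.2e-17) responded less in differentiated TSCs; among NF-κB genes 2 of 27 were higher and 22 were lower (2 and 23 adjusted over the list alone, camera adjusted p = 1.0e-31, down). Among cytokines 13 of 14 were lower (13 adjusted over the list alone, camera adjusted p = 9.6e-18, down). In cholesterol synthesis 18 of 21 were higher (19 adjusted over the list alone, camera adjusted p = 7.8e-16, up). With IFNγ, Apol6 (log2 difference -4.47, SE 0.22, adjusted p = 6.9e-20), the class I transactivator Nlrc5 (-3.26, SE 0.28, adjusted p = 2.8e-12), Stat1 (-2.51, SE 0.13, adjusted p = 3.2e-19) and H2-K1 (-2.14) responded less, and Irf1 responded more (0.60, SE 0.11, adjusted p = 1.7e-04). Gbp2b rose from 1.66 ± 0.68 to 42.8 ± 1.6 CPM in differentiated TSCs and stood near the floor in MEFs, at 0.0427 ± 0.074 and 0.0833 ± 0.072, so the size of its difference depends on the pseudocount. In antigen processing 19 of 21 were lower (20 adjusted over the list alone, camera adjusted p = 5.0e-61, down). Among antiviral genes 1 of 27 was higher and 19 were lower (1 and 23 adjusted over the list alone, camera adjusted p = 1.7e-28, down). Among GTPases 1 of 7 was higher and 4 were lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.0035, down, adjusted p = 0.062 with an estimated correlation). In the cell cycle list 15 of 30 were lower (1 higher and 15 lower adjusted over the list alone, camera adjusted p = 3.0e-07, down, adjusted p = 0.069 with an estimated correlation). Among mitochondrially encoded genes 2 of 13 were lower (4 adjusted over the list alone, camera adjusted p = 0.0030, down, adjusted p = 0.37 with an estimated correlation). With both cytokines Nos2 (-5.45, SE 0.11, adjusted p = 5.5e-31) and the uridine phosphorylase gene Upp1 (-4.84) responded less, and Kif26b more (5.08). The counts were 3437 genes with TNFα (1701 higher and 1736 lower), 1524 with IFNγ (806 and 718) and 5620 with both (2981 and 2639). With library totals alone the last 2 were 567 higher and 934 lower, and 3836 higher and 2048 lower.

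Differentiated TSCs were last compared with TSCs. With IFNγ the response was larger in differentiated TSCs for Gbp7 (log2 difference 3.46, SE 0.21, adjusted p = 1.8e-16), Irgm1 (3.42, SE 0.20, adjusted p = 7.2e-16), Irf1 (2.62, SE 0.11, adjusted p = 2.1e-21), Tap1 (2.49), Psmb9 (3.32), Icam1 (1.48) and B2m (0.85), while Stat1 was not called (0.45, SE 0.13, adjusted p = 0.079; adjusted p = 0.0148 with a pseudocount of 1 CPM and adjusted p = 0.0464 without the 3 libraries that stood apart). Among GTPases 7 of 7 were higher (7 adjusted over the list alone, camera adjusted p = 1.8e-43, up). For 2 of these, Gbp2 and Gbp2b, with 5 and 8 reads in TSC controls, the pseudocount held down the rise in TSCs. Their differences (2.47 and 2.70) were 1.02 and 1.85 with a pseudocount of 0.1 CPM (adjusted p = 0.399 and adjusted p = 0.10) and 0.32 and 1.19 with DESeq2 (adjusted p = 0.872 and adjusted p = 0.349), and edgeR did not call them either (adjusted p = 0.914 and adjusted p = 0.498). Among antiviral genes 13 of 27 were higher (19 adjusted over the list alone, camera adjusted p = 1.6e-39, up). In antigen processing 11 of 21 were higher (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.5e-30, up). In JAK-STAT signalling 6 of 20 were higher (10 adjusted over the list alone, camera adjusted p = 7.9e-13, up). The difference in the response of mitochondrially encoded genes was not called (camera adjusted p = 0.16). With TNFα the 3 genes called, Nfkbia (-0.44, SE 0.077, adjusted p = 0.012), Nfkb2 (-0.34, SE 0.061, adjusted p = 0.012) and Jun (-0.41, SE 0.080, adjusted p = 0.034), responded less in differentiated TSCs, and among NF-κB genes 2 of 27 were lower (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 1.3e-04, down); p53 targets were lower as a list (adjusted p = 0.028). The call of Nfkbia ended without TNFα A of the TSCs, that of Nfkb2 without that library or control A of the TSCs, and that of Jun without control A, control B, TNFα A or TNFα C of the TSCs or control C, TNFα A or TNFα B of the differentiated TSCs. With both cytokines Nfkbia (-0.49, SE 0.077, adjusted p = 2.5e-05) and Relb (-0.69, SE 0.11, adjusted p = 6.1e-05) responded less and Gbp7 more (3.78). The counts were 3 genes with TNFα (all lower), 187 with IFNγ (164 higher and 23 lower) and 289 with both (206 and 83). The first was 271 without control A and 8 without control B of the differentiated TSCs, 289 without their TNFα C, 5 without control C and 1 without TNFα A of the TSCs, 0 with a fit of these 2 cell types alone, 24 with DESeq2 and 9 with edgeR; the other counts were 584 and 743 without the 3 libraries that stood apart.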

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

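The other splits of the libraries were planned, while the tests of single libraries, transcript length, other cells and read shares were chosen after the results were seen. Direct tests between cell types called genes for each treatment, few of them with TNFα in differentiated TSCs against TSCs. Genes whose response differed between TSCs and MEFs numbered 2607 with TNFα, 1231 with IFNγ and 5436 with both. Between differentiated TSCs and MEFs they numbered 3437, 1524 and 5620, and between differentiated TSCs and TSCs 3 (0 with the compared cell types alone; limma in the fit of all libraries gave 1431 with an unadjusted p below 0.05, edgeR called 9 and DESeq2 24), 187 and 289. Among the panel genes, 3 responded more in differentiated TSCs than in MEFs. Irf1 with IFNγ differed by 0.60 (SE 0.11, adjusted p = 1.7e-04), with adjusted p of 9.3e-08 to 0.0013 over the alternatives. Nfkbia with IFNγ differed by 0.26 (SE 0.077, adjusted p = 0.021); this was 0.22 with library totals alone (adjusted p = 0.067, the alternatives ranging from 0.0017 to 0.074), and was not called without control B, control C or IFNγ C of differentiated TSCs or without control C or IFNγ A of MEFs (0.23, 0.24, 0.23, 0.25 and 0.24). Tnfrsf1a with both cytokines differed by 0.51 (SE 0.059, adjusted p = 1.4e-09), with adjusted p of 2.0e-16 to 2.4e-07 over the alternatives.

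Other groupings of the same libraries were counted for every comparison. With 3 against 3 libraries there are 10 splits, so no share under 0.05 can be reached. The real split gave the highest count, 1 of 10 as large, in all 3 TSC treatments (33, 33 and 114 genes, highest other 1, 2 and 6), in differentiated TSCs with IFNγ (836, other 6) and both (1007, other 9), in MEFs (4464, 2288 and 7470, other 4, 7 and 5) and in the control comparisons (11956, 11932 and 10896, other 1, 1 and 0). In differentiated TSCs with TNFα, 3 of the 10 splits called at least the real 122, and the highest other called 3225; this points to a structure of the samples, with control A, TNFα A and TNFα B on 1 side, the 3 with the lowest slopes over transcript length (-0.083, -0.057 and -0.181).

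For interactions and response differences 30 regroupings were used. With IFNγ against MEFs the real grouping led in TSCs (1 of 30, 1231 against 1179) and differentiated TSCs (1 of 30, 1524 against 989). The next highest kept the real MEF groups, so chance stays undecided. Chance was not excluded for the TNFα response of differentiated TSCs against TSCs (9 of 30, 3 against 1315). The regrouping with 1315 again set the former's control A, TNFα A and TNFα B on 1 side, a structure of the samples. The other differences stay undecided too, as each regrouping as large kept a cell type's real groups. These were TNFα (3 of 30, 2607 against 2742) and both cytokines (4 of 30, 5436 against 5578) in TSCs against MEFs, TNFα (2 of 30, 3437 against 4850) and both (3 of 30, 5620 against 6317) in differentiated TSCs against MEFs, and IFNγ (5 of 30, 187 against 296) and both (4 of 30, 289 against 582) in differentiated TSCs against TSCs. Regroupings that broke up the real groups of both cell types reached at most 1, 0 and 1 genes in TSCs against MEFs, 1017, 1 and 1 in differentiated TSCs against MEFs, and 1315, 1 and 1 in differentiated TSCs against TSCs, for TNFα, IFNγ and both in this order. For interactions, exchanging libraries among the 4 treatments carries the effects of single treatments into the interaction, so the counts do not bear on chance: 30 of 30 in TSCs (0 against 28; 431 genes had an unadjusted p below 0.05 in limma, and edgeR and DESeq2 called 0), 4 of 30 in differentiated TSCs (7 against 4565) and 3 of 30 in MEFs (1282 against 4876).

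The first pattern weighed was the 122 genes called with TNFα in differentiated TSCs. The count rested on single libraries, since it was 9 without TNFα B, 12 without control C, 21 without control B, 2262 without control A and 2067 without TNFα C. Removing each library's trend over transcript length left 46 of the 122 genes called. This result picked them, so it cannot weigh that trend as a cause. For the 76 genes whose calls ended, the median size of the log2 difference went from 0.254 to 0.192, a ratio of 0.756, while the median SE went from 0.0638 to 0.0553; a smaller difference ended the calls, and the trend and the treatment cannot be told apart for them, since the ratio lies between the bounds set for and against the trend, and the slopes of TNFα A, B and C (-0.057, -0.181 and -0.0134) and control A (-0.083) were below 0 while those of controls B and C (0.0382 and 0.0338) were above it. A TNFα effect in these cells stays open, as does a difference in RNA handling between libraries, which was not tested.

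The second pattern was the 30 genes that IFNγ raised in TSCs, since differentiated or fibroblast cells in the culture could bring such a response. Of the 30 genes 27 also rose in differentiated TSCs, and to give the rise seen these cells would have to make up 15.4% of the culture (median, quartiles 8.36 and 29.2%), whereas Prl2c2 put their share at 1.17% (upper bound 1.47%). For fibroblasts the share needed was 2.90% (quartiles 1.08 and 5.12%), whereas Postn, the lowest of 19 markers, gave an upper bound of 0.0299% and Col1a1 a share of 0.0259%. The median over these markers was 0.379%, and Sparc gave 25.9%. Both sources are argued against, on the assumption that mixed-in cells respond as they do alone. A response of TSCs themselves stays open as a hypothesis, and so does a change in a share of TSCs that lack these markers, which was not tested.

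The third pattern was the lower share of mitochondrially encoded transcripts with IFNγ, from 1.54 ± 0.041% to 1.32 ± 0.081% of reads in TSCs and from 1.44 ± 0.062% to 1.11 ± 0.042% in differentiated TSCs (SD, n = 3), below all controls in 3 of 3 treated libraries of each. Reads added by raised genes came to 0.0184% and 1.44% of the library, against relative falls of 14.8% and 22.7%, which argues against a share taken up by raised genes. After the trend over transcript length was removed the medians were -0.251 and -0.343, which argues against that trend. In MEFs the share went only from 0.910 ± 0.014% to 0.866 ± 0.057%, a relative fall of 4.84%, below all controls in 2 of 3 treated libraries, with reads added by raised genes at 3.84% and a median of -0.0903 after the trend was removed. A change in mitochondrial transcripts with IFNγ in TSCs and differentiated TSCs is a hypothesis that stays open, and so does a difference in RNA capture, which was not tested.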

How the results depend on the processing

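The planned test was edgeR. Pseudocounts of 0.1 and 1, removal of the length trend and fits without 3 libraries that stood apart were chosen after the results were seen. All 24 counts of called genes stayed within 1.5 times with median-ratio factors, library totals alone, no filter and a pseudocount of 1. Other settings moved some counts, and the cause was not tested unless stated.

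With the compared cell types alone, counts rose to 53 (TNFα) and 255 (both) in TSCs, 25 and 87 shared with all libraries. They fell to 0, 361 and 458 (TNFα, IFNγ, both) in differentiated TSCs, 334 and 413 shared for the last pair. They were 0 for the interaction in differentiated TSCs, 2180 for that in MEFs, and 0 for the TNFα response of differentiated TSCs against TSCs. Variance shared by cell types may thus call too many genes in differentiated TSCs. For the counts of 0, limma in the fit of all libraries gave 2822, 1811 and 1431 genes with an unadjusted p below 0.05. DESeq2 gave 755 for TNFα in differentiated TSCs (110 shared), 12 for their interaction and 24 for their TNFα response against TSCs, for which edgeR gave 127, 1 and 9. A pseudocount of 0.1 gave 16 for that interaction. With the length trend removed they were 50 for TNFα in TSCs, 64 for TNFα in differentiated TSCs and 8 for the TNFα response of these against TSCs.

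The sources used here do not say whether library letters pair the samples. After group means were removed, the median correlations between libraries of the same letter were 0.00163, 0.0168 and -0.00685 in MEFs, TSCs and differentiated TSCs, and 5, 8 and 1 of 12 libraries had their best match at their own letter. No pairing was therefore in the model, and a fit with letters as a block was run beside it. With the block the counts were 63 (20 higher and 43 lower) for TNFα in differentiated TSCs and 5 for their TNFα response against TSCs. The interaction in differentiated TSCs kept a count of 7 (6 higher and 1 lower), of which 5 were shared; Twist2 and Dlk1 were not among them (adjusted p = 0.0554 each).

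Without the 3 libraries that stood apart the counts were 50 for TNFα in TSCs, 2 for their interaction, 8, 1558 and 1750 for TNFα, IFNγ and both in differentiated TSCs (3, 757 and 916 shared), and 584 and 743 for the IFNγ and combined responses of differentiated TSCs against TSCs. With control A of differentiated TSCs left out in place of control C, the counts were 60 and 51 for TNFα and IFNγ in TSCs, 1 for their interaction, 641 for TNFα in differentiated TSCs (100 shared), 286 for the interaction there and 157 for their TNFα response against TSCs, and the other 14 counts stayed within 1.5 times. A minimum of 2-fold keeps fewer genes by construction. For TNFα, IFNγ and both it left 0, 11 and 12 in TSCs, 1, 73 and 76 in differentiated TSCs and 406, 223 and 1186 in MEFs. It left 2 and 144 for the interactions in differentiated TSCs and MEFs. For response differences it left 429, 249 and 1199 for TSCs against MEFs, 445, 211 and 1209 for differentiated TSCs against MEFs and 0, 61 and 63 for differentiated TSCs against TSCs, and it left 5791, 5783 and 3686 for the control comparisons. In the pair of results at 0 the same limma fit had 616 and 1431 genes with an unadjusted p below 0.05.

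Leaving out 1 library at a time (the remaining pair is assumed to vary like the other groups) gave 19 to 30 genes for TNFα, 22 to 33 for IFNγ and 74 to 93 for both in TSCs. It gave 9 to 2262, 507 to 948 and 583 to 1148 in differentiated TSCs; 3787 to 3880, 1822 to 2015 and 6800 to 6924 in MEFs. It gave 0 to 1, 4 to 752 and 1009 to 1220 for the interactions in TSCs, differentiated TSCs and MEFs. Response differences gave 2273 to 2377, 958 to 1284 and 5046 to 5212 for TSCs against MEFs, 2813 to 4087, 1273 to 1541 and 5206 to 5532 for differentiated TSCs against MEFs, and 1 to 289, 148 to 226 and 204 to 339 for differentiated TSCs against TSCs. Control comparisons gave 11724 to 11756, 11702 to 11766 and 10513 to 10599. Of 216 such counts 25 moved beyond 1.5 times; the libraries are named beside the comparisons in the report.

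Ccl2 changed sign in its response in TSCs against MEFs, where it had 1 control read in TSCs, so its fold rests on the pseudocount or prior. With TNFα it was 2.32 with DESeq2 (adjusted p = 0.202) and 1.95 with edgeR (adjusted p = 0.136), and with IFNγ 3.02 with edgeR (adjusted p = 0.0113). With both it was 2.89 with DESeq2 (adjusted p = 0.0451), 2.51 with edgeR (adjusted p = 0.0115) and 0.50 with a pseudocount of 0.1 (adjusted p = 0.41). The values reported were -1.11, -0.09 and -1.05, so 3 values in the opposite direction passed the threshold. In TSCs alone the read ratios were 18.0 (17 against 1 read, interval 2.83 to 754), 19.7 (19 against 1, 3.14 to 820) and 36.5 (36 against 1, 6.14 to 1481).

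Of 2645 values of named genes 7 lost and 3 gained their call with median-ratio factors, 34 and 10 with library totals, 11 and 1 with no filter, 33 and 3 with the block, 127 and 19 with edgeR, 80 and 5 with a pseudocount of 0.1, 14 and 10 with a pseudocount of 1, and 20 and 11 with the length trend removed. It was 116 and 26 of 2603 with the compared cell types alone, 89 and 32 of 2577 with DESeq2, 53 and 17 of 2222 without the 3 libraries, 37 and 25 of 2222 with control A left out in place of control C, and 853 and 78 of 23754 with 1 library left out. Of 576 list tests 73 lost their call with an estimated correlation, 7 lost and 10 gained it with library totals, 1 gained it with median-ratio factors, 5 with no filter and 2 with the block, and 14 lost and 9 gained it of 572 with the compared cell types alone. Depth limits genes with few reads: 1 read was 0.0528 to 0.0715 CPM.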

Other observations

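All lists here were fixed before the data were examined, and the ribosomal RNA values were picked out after they were seen. Some marker lists described cell types other than those cultured. With both cytokines in MEFs, among macrophage and leukocyte markers 3 of 8 rose (3 adjusted over the list alone, camera adjusted p = 0.31), with Cd14, a lipopolysaccharide co-receptor, at 1.54 (SE 0.21, adjusted p = 5.8e-08) and the integrin Itgb2 at 1.30. Among pluripotency genes 3 of 6 fell (3 adjusted over the list alone, camera adjusted p = 0.41), with Klf2 at -0.34. Of the extraembryonic endoderm markers 1 of 10 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.30), with the matrix gene Sparc at -0.48 (SE 0.034, adjusted p = 6.1e-16). Of the endothelial markers 2 of 7 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.93), with the endothelial transcription factor Erg at -1.63. In control TSCs against MEFs 3 of 8 were higher and 3 were lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.83) among macrophage and leukocyte markers, and Cd14 stood at -3.85 (SE 0.21, adjusted p = 1.7e-20). For pluripotency genes 4 of 6 were higher and 2 were lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.41), with Esrrb, which TSCs also express, at 6.39 (SE 0.21, adjusted p = 3.1e-25). For extraembryonic endoderm markers 4 of 10 were higher and 6 were lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.85), with Sparc at -2.45. For endothelial markers 5 of 7 were higher and 1 was lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.046, up, adjusted p = 0.075 with an estimated correlation), Pecam1 at 5.77 among the former; the list had adjusted p = 0.0931 with library totals alone.

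Ribosomal RNA differed between libraries of the same group. Rn18s ranged from 1101 to 18841 CPM in TSCs with both cytokines, the highest being combination B, and from 1149 to 2911 CPM in TSCs with IFNγ, against 1207 to 1311 in control TSCs.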
